A study of Mus musculus with 32 samples.

How the data were processed

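Total RNA of mouse liver was hybridised to Affymetrix Mouse Gene 2.1 ST arrays, 1 array for each of 32 mice, after extraction with miRNeasy columns and DNase, whole-transcript amplification and biotin labelling, per the labels' protocols. The deposited log2 values were made by the authors with RMA in Affymetrix Expression Console 1.3.0.187, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set, so that a difference of 1 between values is a 2-fold difference in signal and low values are compressed towards the background. The values were used as deposited. Scanner files were not used here.

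The table held 41345 probe sets. A platform annotation paired 23521 of them with 1 gene symbol and 1814 with several, and 16010 were not listed in it and stay unnamed. Entrez identifiers of 23328 probe sets matched a reference gene table, which changed 0 symbols. Probe sets with 1 symbol were analysed, and of several probe sets of a gene (1082 genes) the one with the highest mean over all arrays was taken, which left 22180 genes. Of the 10 anchor genes chosen beforehand, 1 is not analysed here.

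Groups came from the titles of the samples: palm oil or control gavage, each basal or clamped. The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 32 arrays with 1 mean per group, which leaves 28 residual degrees of freedom shared by 5 contrasts: palm oil minus control in basal and in clamped mice, clamped minus basal in control and in palm oil mice, and the interaction. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05, and intervals are at 95%. Every adjusted p of a gene comes from this limma fit, and values after ± are standard errors. Each array is a separate mouse, so that the spread covers differences between animals.

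Lists of genes, 26 of pathways and 14 of cell types, were fixed before the data were examined. The 39 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 39 lists of a contrast. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance 1 way, and compares no list with other genes. The members past a threshold were also counted when adjusted over the list alone.

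Genes named in the text followed a rule fixed beforehand. They were the 6 genes with the largest rise and the 6 with the largest fall past the threshold in each contrast, leaving out predicted gene models and small RNAs. Up to 3 members with the smallest p were taken of each list that passed or had at least 3 called members, of which the text leaves some out. The anchor genes of lipid and glucose handling were named whether past the threshold or not. Exceptions are stated where they occur.

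The functions were tested on simulated data made from the mean of each gene over all arrays and the real residuals, shuffled as whole arrays, in 20 draws of 22180 genes. In each draw 50 genes per fold size, from the brighter part of the genes, were changed. For palm oil minus control in basal mice, 8.00% of 1.25-fold, 52.0% of 1.5-fold, 90.5% of 2-fold and 98.5% of 3-fold changes were recovered, and 4.38% of calls were false. In clamped mice the shares were 9.10%, 50.1%, 92.8% and 99.4%, with 4.08% false calls. For clamped minus basal they were 6.40%, 43.3%, 89.6% and 98.5% in control mice, with 4.38% false, and 11.7%, 60.0%, 93.7% and 98.6% in palm oil mice, with 5.07% false. For the interaction they were 1.30%, 20.0%, 69.4% and 94.3%, with 3.55% false. The shuffling spreads any batch over all groups. In the data the 7 basal arrays numbered 44 or higher, with a narrower spread of values, lie in the basal groups alone. The shares of false calls therefore do not cover a batch that falls unevenly on the groups. Without any change, camera with the preset correlation passed on average between 6.45 and 8 of 39 lists in these comparisons, and with an estimated correlation at most 0.15. Calls of lists with the preset correlation alone are therefore given with the estimated value beside them.

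The alternatives tried were the brighter part of the genes, the mean of all probe sets, 1 median for all arrays, repeated quantile normalization, a trend or a robust prior, array weights, the replicate number as a block, the animal number as a term (centred within basal and within clamped mice, whose numbers do not overlap), the compared groups alone, a threshold of 0.1, a minimum of 1.3-fold, every row of the table, an exact rank sum test and leaving out each array in turn. After the arrays' spread and the acinar markers had been seen, the split of the basal arrays at animal 44 (as a block, left out, and within each part) and the acinar marker level (as a term, and without arrays over 6 log2 units) were added.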

Results

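Liver RNA of 14-week-old male C57BL/6NTac mice was measured on 32 Affymetrix Mouse Gene 2.1 ST arrays, with 1 array per mouse. Mice fasted for 10 h received palm oil, a fat rich in saturated fatty acids, at 2 g/kg by gavage, or water as the control. Liver was taken either 6 h after the gavage (basal mice) or at the end of a hyperinsulinemic-euglycemic clamp begun at 6 h, in which insulin was infused at 15 pmol/kg/min while blood glucose was held steady. Clamped mice also received a tracer before the insulin (110 min). The 4 groups held 9 palm oil basal, 7 control basal, 9 palm oil clamped and 7 control clamped mice. Values are log2 expression values. Array medians lay between 1.65 and 1.77, and the number of arrays, not a sequencing depth, limits the precision.

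The arrays differed in ways that the treatment did not define. The 7 basal arrays of animals numbered 44 or higher, 3 of them palm oil and 4 control, had interquartile ranges of 2.44 to 2.54, against 2.72 to 2.96 in the other 9 basal arrays and 2.64 to 2.85 in the clamped arrays. Transcripts of pancreatic acinar cells, such as Ctrb1 (chymotrypsinogen) and Cel (carboxyl ester lipase), averaged over 6 log2 units in 12 of the 32 arrays. These were 5 palm oil basal, 4 control basal, 2 palm oil clamped and 1 control clamped array. As a list, the 9 measured acinar markers were lower in clamped than in basal mice, with a median log2 difference of -3.30 in control and -2.90 in palm oil mice. No member passed the test over all genes, all 9 fell when adjusted over the list alone, and the list had an adjusted p = 0.396 in control and 0.343 in palm oil mice with an estimated correlation. Over all genes Ctrb1 passed in control mice without control basal replicate 3 (-5.24) or control clamped replicate 3 (-5.66), as did Cel (-4.32 and -4.58). Ctrb1 passed in palm oil mice without palm oil basal replicate 1 (-4.56).

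**Figure D1:**
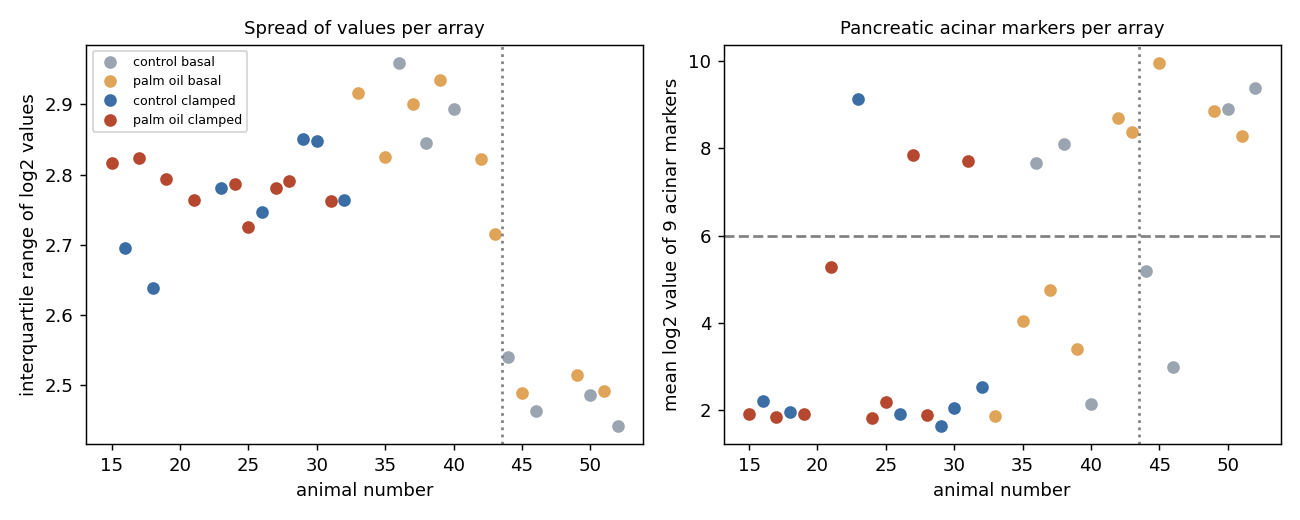
Interquartile range of the log2 values of each array (left) and mean log2 value of 9 pancreatic acinar markers (right) against the animal number, 1 point per array, coloured by group. The 7 basal arrays to the right of the dotted line have interquartile ranges of 2.44 to 2.54, and 12 arrays lie above the dashed line at 6 log2 units.

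The first question was whether palm oil had changed liver expression by 6 h in mice that were not clamped. No gene of the 22180 tested differed between palm oil and control basal mice. Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, differed by -0.10 ± 0.10 (log2, SE, n = 9 and 7), and Cpt1a, which admits long-chain fatty acids to mitochondria, by 0.09 ± 0.10. Pdk4, an inhibitor of pyruvate dehydrogenase, differed by 0.46 ± 0.24 (limma adjusted p = 0.975), and Fgf21, a fasting hormone, by 0.43 ± 0.25 (limma adjusted p = 0.977). The differences of G6pc (glucose-6-phosphatase), Igfbp1 (an insulin-like growth factor binding protein), Irs2 (an insulin receptor substrate), Srebf1 (a regulator of lipogenesis) and Cyp7a1 (the rate-limiting enzyme of bile acid synthesis) lay between -0.12 and 0.15, each within its SE. The 95% interval excluded a 2-fold difference in array values for 98.9% of the genes. That share includes dim genes (median log2 value over all genes 1.83), whose differences are compressed towards the background. For those it does not exclude a 2-fold change in RNA.

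Chaperone genes lay higher as groups in the palm oil basal mice under the preset correlation of the list test, without a member called over all genes. The 21 measured genes of the unfolded protein response had a median log2 difference of 0.24 and an adjusted p = 6.73e-06, against an adjusted p = 0.947 with an estimated correlation. Among them, Pdia3 differed by 0.33 ± 0.14 and Sdf2l1 by 0.75 ± 0.35. The 16 measured heat shock genes had a median of 0.13 and an adjusted p = 4.38e-04, against an adjusted p = 0.947 with an estimated correlation. Adjusted over the list alone, 3 heat shock genes and no unfolded protein response gene passed. Stip1 differed by 0.39 ± 0.11, Hsp90aa1 by 0.42 ± 0.12 and Hsph1 by 0.46 ± 0.16, the values with the smallest p of that list. In simulated data without any change for this comparison, the preset correlation passed 8 of 39 lists on average, so that 2 lists lie below what no effect gave there. Without the 7 basal arrays numbered 44 or higher, neither the unfolded protein response (adjusted p = 0.183) nor heat shock genes (adjusted p = 0.0888) passed, and ribosome biogenesis genes did (adjusted p = 0.00310).

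With limma, 1134 genes had an unadjusted p under 0.05, where 1109 were expected, and the smallest adjusted p was 0.300. That count was 2081 without the 12 arrays high in acinar markers and 695 without the 7 basal arrays numbered 44 or higher, settings chosen after the data were seen. The exact rank sum test also called 0 genes, with 774 at an unadjusted p under 0.05. The smallest changes simulated were called in 8% of cases, so that most differences of that size would be missed. No gene was called within the 7 basal arrays numbered 44 or higher, within the other 9, or with the split as a block. Counts of 1 arose without control basal replicate 1 (Cops7b, 0.88 ± 0.15), without control basal replicate 3 (Mir1968, -0.59 ± 0.10) and without the 12 arrays high in acinar markers (Brca2, 1.37 ± 0.21), genes named because they made up these counts.

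The same comparison under the clamp asked whether palm oil altered the liver under high insulin. Again no gene differed between palm oil and control clamped mice. Cyp7a1 had a log2 difference of 1.14 ± 0.50 (SE, n = 9 and 7) and Cyp8b1, which makes cholic acid, of 0.68 ± 0.31, neither past the test. Acot1, an acyl-CoA thioesterase, differed by 0.63 ± 0.25 and Kdr, a receptor of vascular endothelial growth factor, by 0.53 ± 0.19. Without control clamped replicate 6 the differences were 0.55 for Cyp7a1, 0.27 for Cyp8b1 and 0.35 for Acot1. Pck1 differed by 0.04 ± 0.10, Srebf1 by 0.04 ± 0.15, Igfbp1 by 0.06 ± 0.34, Pdk4 by 0.12 ± 0.24, Cpt1a by 0.18 ± 0.10, Fgf21 by 0.37 ± 0.25, Irs2 by 0.37 ± 0.29 and G6pc by 0.52 ± 0.50. The 95% interval excluded a 2-fold difference in array values for 99.0% of the genes. As in the basal mice, the share includes dim genes, for which a 2-fold change in RNA is not excluded.

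Under the preset correlation, 8 lists passed in the clamped mice and 0 with an estimated correlation. Bile acid synthesis genes had a median log2 difference of 0.14 (adjusted p = 3.36e-04, and adjusted p = 0.589 with an estimated correlation). Targets of PPARA, the fatty acid sensor, had a median of 0.13 (adjusted p = 5.66e-04, and adjusted p = 0.589 with an estimated correlation). Beta-oxidation genes had one of 0.09 (adjusted p = 0.00113, and adjusted p = 0.610 with an estimated correlation). Lipogenesis genes had a median of 0.12 (adjusted p = 0.0232, and adjusted p = 0.610 with an estimated correlation). Endothelial markers had a median of 0.13 (adjusted p = 4.31e-04, and adjusted p = 0.589 with an estimated correlation). Kupffer cell markers had one of 0.16 (adjusted p = 0.0200, and adjusted p = 0.589 with an estimated correlation). Ribosome biogenesis genes had a median of -0.10 (adjusted p = 5.44e-04, and adjusted p = 0.589 with an estimated correlation). Cholesterol synthesis genes had one of -0.15 (adjusted p = 0.0226, and adjusted p = 0.807 with an estimated correlation). No member of any of these lists passed, over all genes or adjusted over the list alone. In simulated data without any change for this comparison, 6.7 of 39 lists passed on average with the preset correlation. Without the 12 arrays high in acinar markers, PPARA targets (adjusted p = 0.0829), beta-oxidation (0.0829) and lipogenesis genes (0.189) did not pass. The unfolded protein response, glycogen and xenobiotic metabolism lists did (adjusted p = 0.0465 each). Without the 7 basal arrays numbered 44 or higher, lipogenesis and cholesterol synthesis genes did not pass (adjusted p = 0.0514 each).

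With limma, 781 genes had an unadjusted p under 0.05 against 1109 expected, and the exact rank sum test called 0 genes, with 723 at an unadjusted p under 0.05. The smallest changes simulated were called in 9.10% of cases. Across genes, which are not independent replicates, the palm oil differences in basal and in clamped mice correlated with a Pearson r of 0.035 and a Spearman rho of 0.027.

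Whether the palm oil difference itself changed under the clamp was tested as an interaction. No gene passed. The interaction was 0.99 ± 0.71 for Cyp7a1, 0.62 ± 0.71 for G6pc, 0.34 ± 0.41 for Irs2, -0.34 ± 0.33 for Pdk4, 0.15 ± 0.21 for Srebf1, 0.14 ± 0.14 for Pck1, 0.09 ± 0.14 for Cpt1a, -0.07 ± 0.35 for Fgf21 and -0.01 ± 0.48 for Igfbp1 (log2, SE, n = 9, 7, 9 and 7). The value of Cyp7a1 rests in part on control clamped replicate 6, without which its palm oil difference in clamped mice was smaller. The unfolded protein response list had a median interaction of -0.31 (adjusted p = 1.42e-06, and adjusted p = 0.932 with an estimated correlation), with 1 of 21 members above 0. Heat shock genes had a median of -0.23 (adjusted p = 0.00749, and adjusted p = 0.932 with an estimated correlation) and cholesterol synthesis genes one of -0.28 (adjusted p = 0.00714, and adjusted p = 0.932 with an estimated correlation). Bile acid genes had a median of 0.14 (adjusted p = 0.00714, and adjusted p = 0.932 with an estimated correlation) and beta-oxidation genes one of 0.12 (adjusted p = 0.00784, and adjusted p = 0.932 with an estimated correlation). No member of these lists passed over all genes or adjusted over the list alone. With limma, 773 genes had an unadjusted p under 0.05 against 1109 expected, and 1503 without the 12 arrays high in acinar markers. Without those arrays, bile acid (adjusted p = 0.849) and beta-oxidation genes (0.691) did not pass, and PPARA targets (0.00990) and acute phase genes (1.44e-04) did. Without the 7 basal arrays numbered 44 or higher, cholesterol synthesis (adjusted p = 0.462) and heat shock genes (0.107) did not. The interval excluded a 2-fold interaction in array values for 95.2% of genes, dim ones included, for which it says little about RNA. Simulated 2-fold interactions, in the brighter part of the genes, were recovered in 69.4% of cases. Without control basal replicate 1, 1 gene passed, Cops7b (-1.20 ± 0.20), named because it was that count.

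In control mice, the clamped liver differed from the basal liver in 1940 genes, of which 1033 rose and 907 fell. The largest rises were those of Lcn2, the iron-binding lipocalin 2 (4.50 ± 0.38, 22.6-fold, n = 7 and 7), Egr1, an immediate early transcription factor (4.38 ± 0.41, 20.8-fold), Igfbp1 (3.81 ± 0.36, 14.1-fold), the acute phase apolipoproteins Saa2 (3.79 ± 0.42) and Saa3 (3.67 ± 0.46), and the neutrophil protein S100a8 (3.58 ± 0.37). The largest falls were those of G0s2, an inhibitor of adipose triglyceride lipase (-2.91 ± 0.19), Cyp2b9 (-2.54 ± 0.57), G6pc (-2.44 ± 0.53), Cyp7a1 (-2.25 ± 0.53), the antisense transcript Hnf4aos (-2.16 ± 0.25) and the steroid dehydrogenase Hsd3b2 (-2.14 ± 0.38). All 7 clamped arrays lay above every basal array for Lcn2, Egr1, Igfbp1, Saa2 and S100a8, and below every one for G0s2 and Cyp2b9. For G6pc 6 of 7 did so, and for Cyp7a1 5 of 7. The control clamped values of Cyp7a1 ran from 2.354 to 7.814. Its fall rests in part on control clamped replicate 6, without which the control clamped mean was higher. Without the 12 arrays high in acinar markers, G6pc (-2.57, adjusted p = 0.0866), Cyp7a1 (-2.36, adjusted p = 0.0913) and Cyp2b9 (-2.17, adjusted p = 0.151) did not pass in limma. The exact rank sum test gave an adjusted p = 0.196 for G6pc and 0.0916 for Cyp7a1.

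**Figure D2:**
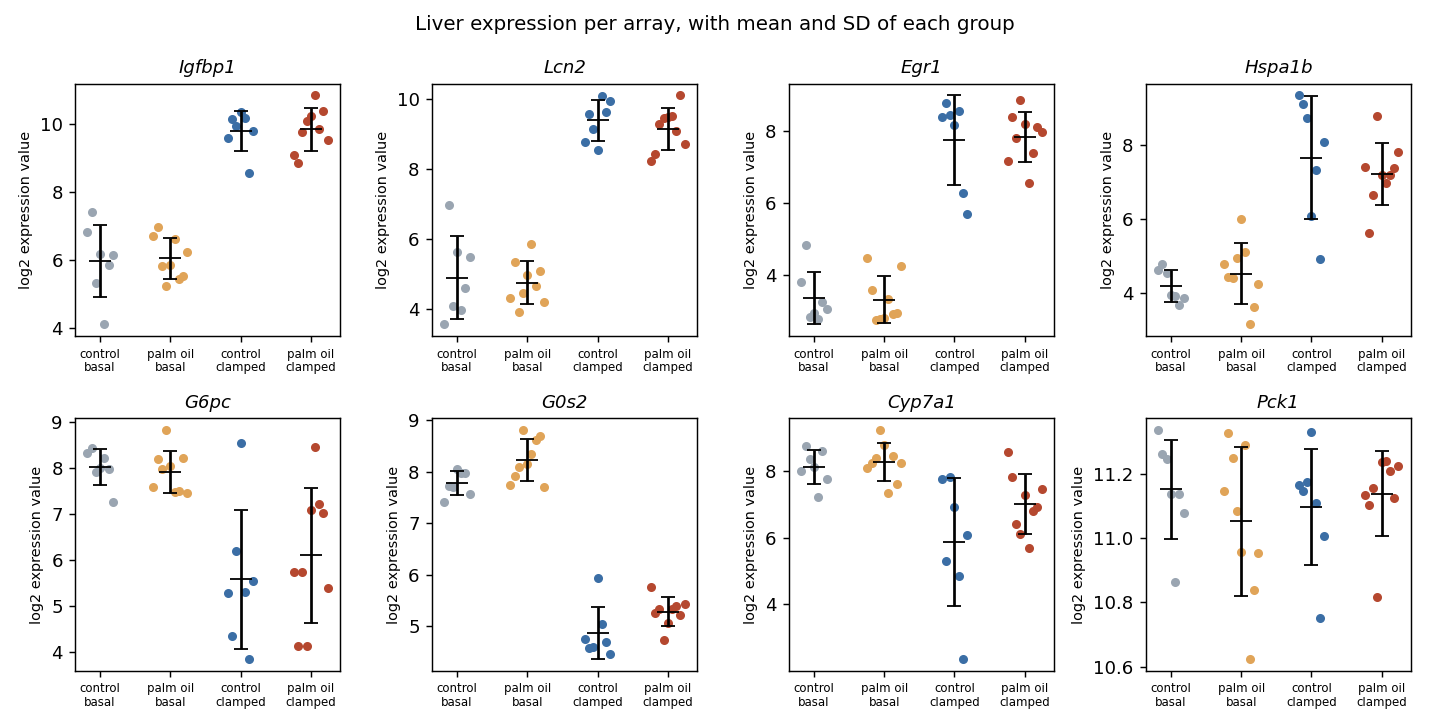
Log2 expression values of 8 genes in the 4 groups (9 palm oil and 7 control mice in each state), 1 point per array, with the mean and SD of each group as a black bar; the vertical axes are scaled per gene and do not start at 0. Igfbp1 and Lcn2 are higher in every clamped array than in any basal array, G0s2 is lower in every one, and the ranges of Pck1 overlap in all groups.

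Genes of the acute phase response, the liver's response to inflammation, rose in control mice for 25 of 27 measured members (27 adjusted over the list alone). Their median difference was 0.91 (adjusted p = 2.85e-46, and adjusted p = 0.00123 with an estimated correlation). Examples were Il1r1, the interleukin 1 receptor (2.15 ± 0.18), and Steap4 (2.47 ± 0.25). Of 21 immediate early genes 15 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 0.00251 with an estimated correlation), with Btg2 at 3.46 ± 0.31 and Jun at 2.95 ± 0.30. Glucocorticoid receptor targets rose for 12 of 20 members and fell for 1 (13 and 1 adjusted over the list alone; adjusted p = 0.00388 with an estimated correlation), among them Cdkn1a, a cell cycle inhibitor (3.18 ± 0.30), and the metallothionein Mt2 (1.19 ± 0.15). Of 16 heat shock genes 12 rose (13 adjusted over the list alone; adjusted p = 0.00578 with an estimated correlation), led by Hspa1b, an inducible chaperone (3.46 ± 0.49). The unfolded protein response rose for 17 of 21 members (20 adjusted over the list alone; adjusted p = 0.0232 with an estimated correlation), including Ddit3 (1.24 ± 0.22) and Pdia3 (0.73 ± 0.15). ATF4 targets rose for 5 of 20 members, also adjusted over the list alone (adjusted p = 0.00497 with an estimated correlation), such as Ddit4 (2.26 ± 0.32) and Chac1 (1.26 ± 0.21).

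Toll-like receptor and NF-kappaB genes rose for 12 of 29 members and fell for 1 in control mice (14 and 1 adjusted over the list alone). The list had an adjusted p = 1.51e-09, and an adjusted p = 0.0612 with an estimated correlation. Its called members included the cytokine Il1b (2.65 ± 0.29), the chemokine Cxcl1 (3.17 ± 0.35) and the lipopolysaccharide co-receptor Cd14 (2.00 ± 0.26). Neutrophil markers rose for 6 of 14 members (7 adjusted over the list alone; adjusted p = 0.00393 with an estimated correlation), with S100a9 at 2.82 ± 0.25 and Retnlg at 1.74 ± 0.24.

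PPARA targets fell for 14 of 21 members and rose for 1 in control mice, the same counts as adjusted over the list alone (median -0.61, adjusted p = 1.33e-11, and adjusted p = 0.0232 with an estimated correlation). Examples were the thioesterase Acot4 (-1.64 ± 0.22) and the transcription factor Creb3l3 (-0.58 ± 0.09), while Pdk4 rose (1.04 ± 0.25), which did not pass with the acinar level as a term (0.78, adjusted p = 0.0552). Beta-oxidation genes fell for 10 of 22 members (16 adjusted over the list alone), among them Decr1 (-0.58 ± 0.11) and Acadm (-0.48 ± 0.09), with an adjusted p = 1.81e-09, and adjusted p = 0.0768 with an estimated correlation. Lipogenesis genes fell for 8 of 22 members, also adjusted over the list alone, with Pklr, the liver pyruvate kinase, at -1.06 ± 0.19 and Srebf1 at -0.82 ± 0.16 (adjusted p = 1.98e-05, and adjusted p = 0.0712 with an estimated correlation). Bile acid genes fell for 10 of 21 members and rose for 1 (13 and 1 adjusted over the list alone), with Hsd3b7 at -0.85 ± 0.12 and Klb, the FGF co-receptor, at -1.31 ± 0.25 (adjusted p = 5.54e-07, and adjusted p = 0.134 with an estimated correlation). Retinoid genes fell for 4 of 20 members (5 adjusted over the list alone; adjusted p = 0.0238 with an estimated correlation), including Dhrs3 (-0.74 ± 0.13) and Rdh16 (-1.01 ± 0.22).

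Among the glucose genes in control mice, G6pc fell and Pck1 differed by -0.05 ± 0.10 (limma adjusted p = 0.838). The list of FOXO1 targets, drawn up as genes lowered by insulin though this need not hold for every member, held 4 members that rose and 1 that fell of 19. Adjusted over the list alone, 5 rose and 2 fell (adjusted p = 0.0220 for the list, and adjusted p = 0.286 with an estimated correlation). Besides Igfbp1, Trib1 (1.17 ± 0.13) and Bcl6 (1.49 ± 0.32) rose in limma. Of the 7 clamped arrays 1 lay above every basal array for Bcl6, which did not pass with the exact rank sum test (adjusted p = 0.196). Irs2 differed by 0.90 ± 0.31 (limma adjusted p = 0.0652), Cpt1a fell by 0.34 on the log2 scale (SE 0.11, limma adjusted p = 0.0375), and Fgf21 differed by -0.43 ± 0.27 (limma adjusted p = 0.386). Cpt1a did not pass without control basal replicate 1, 2, 3 or 4 or control clamped replicate 6 or 7 (-0.34 to -0.27). Nor did it pass with the exact rank sum test (adjusted p = 0.196), the compared groups alone (adjusted p = 0.163), arrays shifted to 1 median (-0.31, adjusted p = 0.0830), array weights (-0.29, adjusted p = 0.0780) or the acinar level as a term (-0.35, adjusted p = 0.0658). Irs2 passed in the brighter part of the genes (adjusted p = 0.0392), with array weights (0.98, adjusted p = 0.0478) and without palm oil clamped replicate 2 or 6, control basal replicate 1 or control clamped replicate 6 (0.90 to 1.06).

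**Figure D3:**
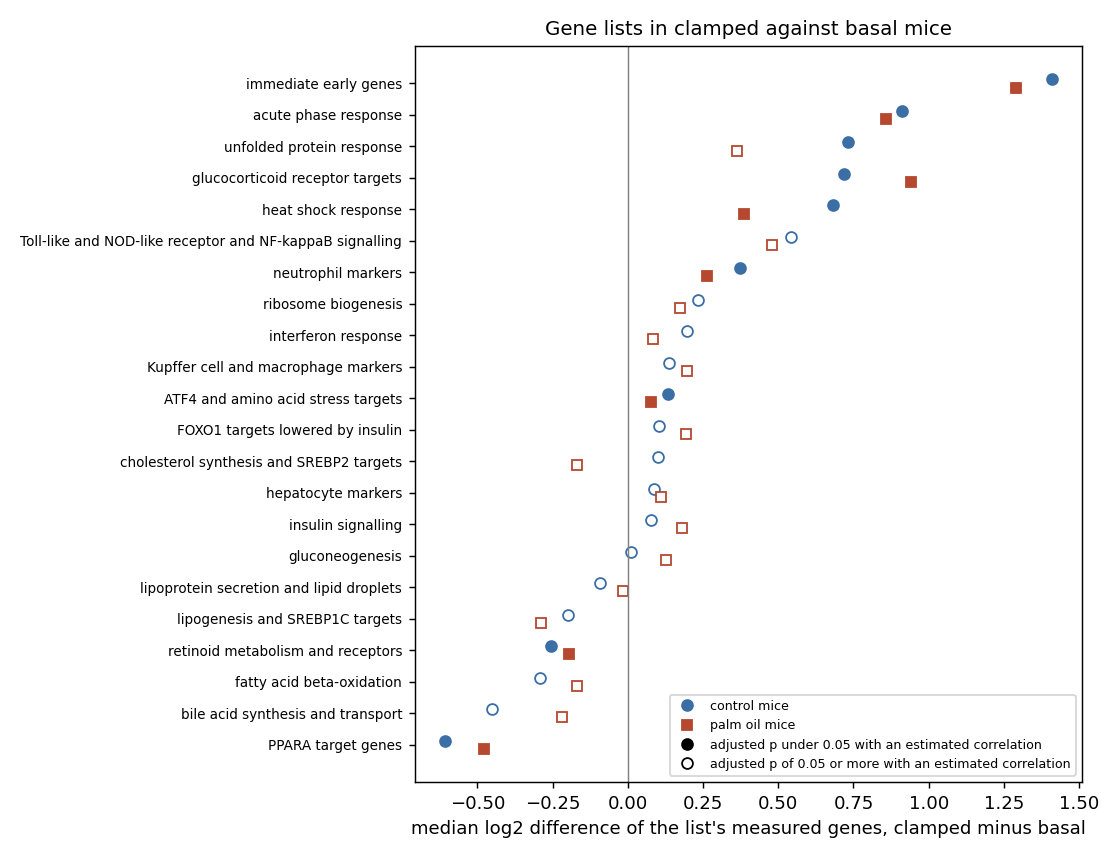
Median log2 difference, clamped minus basal, of the measured genes of each list past an adjusted p of 0.05 with the preset correlation in either treatment, for control mice (circles) and palm oil mice (squares), the acinar markers left out. Filled symbols passed also with an estimated correlation, as acute phase (0.91 and 0.86) and PPARA target genes (-0.61 and -0.48) did, and open symbols did not.

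Clamped and basal mice differed also in catheter surgery 6 to 7 days before, in anaesthetic, in the tracer given before the insulin and in hours since the gavage. They differed in animal number too (15 to 32 clamped, 33 to 52 basal). The comparison therefore covers the whole procedure and any batch that follows that number. Without the 7 basal arrays numbered 44 or higher, which leaves 3 control basal arrays, 1026 genes were called, with 3 unfolded protein response, 6 heat shock and 5 Toll-like receptor risers and 2 lipogenesis fallers, while Cyp7a1 (-2.51), Pklr (-0.76), Ddit3 (0.70), Pdia3 (0.53), Pdk4 (0.84) and Cpt1a (-0.47) did not pass. Without the 12 arrays high in acinar markers, which leaves 3 control basal and 6 control clamped arrays, 993 genes were called. Among them were 5 unfolded protein response, 7 heat shock and 6 Toll-like receptor risers, and 4 PPARA, 1 beta-oxidation, 3 bile acid, 3 lipogenesis and 1 retinoid fallers. Decr1 (-0.47), Klb (-1.17), Rdh16 (-0.88), Pdk4 (1.01) and Cpt1a (-0.30) did not pass.

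In palm oil mice, the clamped liver differed from the basal liver in 1678 genes, of which 835 rose and 843 fell. Egr1 (4.50 ± 0.36, 22.6-fold, n = 9 and 9), Lcn2 (4.40 ± 0.33), S100a8 (3.85 ± 0.32), Igfbp1 (3.80 ± 0.32), Cxcl1 (3.59 ± 0.31) and Saa2 (3.43 ± 0.37) rose most, each in all 9 clamped arrays above every basal array. G0s2 (-2.95 ± 0.17), Cyp2b9 (-2.69 ± 0.50), Hnf4aos (-2.03 ± 0.22), the thioesterase Acot3 (-1.98 ± 0.25), the lectin Clec2h (-1.82 ± 0.34) and G6pc (-1.81 ± 0.47) fell most. G0s2 lay below every basal array in all 9 clamped arrays, G6pc in 8 of 9 and Cyp2b9 in 7 of 9. Irs2 rose by 1.23 ± 0.27 and Pdk4 by 0.69 ± 0.22, and Srebf1 fell by 0.66 on the log2 scale (SE 0.14). The differences of Pck1 (0.09 ± 0.09), Cpt1a (-0.25 ± 0.09), Fgf21 (-0.49 ± 0.23) and Cyp7a1 (-1.26 ± 0.47) did not pass, and neither did the interactions of Irs2, Cpt1a and Cyp7a1. Pdk4, with a limma adjusted p = 0.0478, did not pass without palm oil basal replicate 2, 5, 6, 8 or 9, palm oil clamped replicate 3, 5, 6 or 8, control basal replicate 2, 3, 4, 5 or 7, or control clamped replicate 1 or 2 (0.53 to 0.70). Nor did it pass with array weights (0.59), the compared groups alone, the exact rank sum test (adjusted p = 0.0835) or the acinar level as a term (0.47). Cyp7a1 passed without control clamped replicate 6 (adjusted p = 0.0211), with array weights (-1.28, adjusted p = 0.0466) and with the compared groups alone (adjusted p = 0.0111). Cpt1a passed with array weights (-0.28, adjusted p = 0.0254), with the compared groups alone (adjusted p = 0.0426) and with the exact rank sum test (adjusted p = 0.0175). The rank sum test thus called it in palm oil and not in control mice, the reverse of limma.

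Of the acute phase genes 26 of 27 rose in palm oil mice, also adjusted over the list alone (median 0.86, adjusted p = 2.36e-04 with an estimated correlation), such as Serpina3n (1.06 ± 0.11). Immediate early genes rose for 15 of 21 members (16 adjusted over the list alone; adjusted p = 2.36e-04 with an estimated correlation), including Junb (2.45 ± 0.24). Glucocorticoid receptor targets rose for 15 of 20 (17 adjusted over the list alone; adjusted p = 2.36e-04 with an estimated correlation), including the phosphatase Dusp1 (1.79 ± 0.19). Heat shock genes rose for 8 of 16 members (12 adjusted over the list alone; adjusted p = 0.0159 with an estimated correlation), with Hspa1b at 2.69 ± 0.44. ATF4 targets rose for 6 of 20 (6 with 1 fall adjusted over the list alone; adjusted p = 0.0159 with an estimated correlation), among them Ddit4 (2.47 ± 0.28). Neutrophil markers rose for 6 of 14 (7 adjusted over the list alone; adjusted p = 8.73e-04 with an estimated correlation), with S100a9 at 2.47 ± 0.22. The unfolded protein response rose for 7 of 21 members (12 adjusted over the list alone), with Herpud1 at 0.77 ± 0.13 and Ppp1r15a at 1.07 ± 0.18; the list had an adjusted p = 6.14e-10, and an adjusted p = 0.120 with an estimated correlation. Toll-like receptor and NF-kappaB genes rose for 10 of 29 members and fell for 2 (17 and 3 adjusted over the list alone; adjusted p = 6.14e-10, and adjusted p = 0.0547 with an estimated correlation).

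PPARA targets fell for 11 of 21 members and rose for 1 in palm oil mice (13 and 1 adjusted over the list alone; median -0.48, adjusted p = 0.0267 with an estimated correlation), with Acot4 at -1.76 ± 0.19 and the thiolase Acaa1b at -1.11 ± 0.17. Lipogenesis genes fell for 9 of 22 members (11, with 1 rise, adjusted over the list alone; adjusted p = 4.19e-06, and adjusted p = 0.0547 with an estimated correlation), including the elongase Elovl5 (-0.53 ± 0.11). Beta-oxidation genes fell for 5 of 22 (8 adjusted over the list alone; adjusted p = 8.57e-06, and adjusted p = 0.187 with an estimated correlation), including Eci1 (-0.33 ± 0.09). Bile acid genes fell for 5 of 21 and rose for 1 (9 and 3 adjusted over the list alone; adjusted p = 8.23e-04, and adjusted p = 0.319 with an estimated correlation). Cholesterol synthesis genes fell for 3 of 19, among them Sc5d (-0.60 ± 0.10) and Stard4 (-0.71 ± 0.15), also adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.609 with an estimated correlation). Retinoid genes fell for 6 of 20, also adjusted over the list alone (adjusted p = 0.00338 with an estimated correlation). FOXO1 targets rose for 5 of 19 and fell for 1 (6 and 1 adjusted over the list alone; adjusted p = 5.49e-04, and adjusted p = 0.114 with an estimated correlation). Tat, tyrosine aminotransferase, which is on the gluconeogenesis and glucocorticoid receptor target lists and not on the FOXO1 list, rose by 0.83 ± 0.14.

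The clamp differences of the 2 treatments correlated across genes with a Pearson r of 0.796 and a Spearman rho of 0.561, where genes are not independent replicates and no array is shared. Of 1092 genes called in both, all went the same way: 590 rose, against 38.9 for independent lists, and 502 fell, against 34.5. Both comparisons set clamped mice of lower animal numbers against basal mice of higher ones. A batch that follows that number would also give such agreement, so that it does not tell the clamp from a batch. Leaving out the 12 arrays high in acinar markers keeps 4 palm oil basal and 7 palm oil clamped arrays, so that fewer calls need not mean smaller differences. Without them 736 genes were called in palm oil mice, with 3 unfolded protein response, 3 heat shock, 1 ATF4 target and 2 FOXO1 target risers. There were 5 PPARA, 3 lipogenesis, 1 beta-oxidation, 1 bile acid, 1 cholesterol and 2 retinoid fallers. G6pc (-2.10), Cyp2b9 (-2.51), Irs2 (1.28), Pdk4 (0.50), Eci1 (-0.32), Elovl5 (-0.55) and Stard4 (-0.80) did not pass. Without the 7 basal arrays numbered 44 or higher, 1290 were called, with 4 unfolded protein response, 4 heat shock and 3 FOXO1 target risers, and G6pc (-1.91), Pdk4 (0.50) and Eci1 (-0.30) did not pass. With quantile normalization repeated, 880 genes rose and 1223 fell in control mice, in place of 1033 and 907. In contrast, 1167 rose and 719 fell with the arrays shifted to 1 median. Without the 7 basal arrays numbered 44 or higher, 396 rose and 630 fell in control mice and 529 and 761 in palm oil mice, and without the 12 arrays high in acinar markers 290 rose and 446 fell in palm oil mice.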

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

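The counts of arrays high in acinar markers within the 7 late basal arrays and between basal and clamped mice, the permutation of acinar levels, the reading of Igfbp1 against insulin, the calls in other splits and the sizes of differences after quantile normalization, and the lists of mitochondrially encoded and ribosomal protein genes are tests chosen after the result was seen.

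The clamp comparisons gave more calls than any other split drawn, where 1 of 100 is the smallest share possible. Such splits do not tell the clamp from a batch that follows the animal number. Among 100 splits of the 14 control arrays, the real one included, 1 gave as many calls as the real 1940, and the highest other gave 394. Among 100 splits of the 18 palm oil arrays, 1 gave as many as 1678, and the highest other gave 22. For palm oil in basal mice, palm oil in clamped mice and the interaction the real count was 0, which all 100 of 100 splits reach by construction, so that this count says nothing about chance. The highest other splits gave 2054, 94 and 117. The counts at an unadjusted p under 0.05 are not fixed in this way, and 51, 68 and 97 of 100 splits gave as many as the real 1134, 781 and 773. The make-up of the split with 2054 calls was not examined. Basal arrays numbered under 44 differed from those numbered 44 or higher in 2962 genes, and with that division as a block palm oil called 0 genes.

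Pancreatic acinar markers were high in 12 of 32 liver arrays, with mean log2 values from 1.63 to 9.96 over the arrays and Ctrb1 from 1.35 to 11.4. In control clamped replicate 3 the mean was 9.14, Ctrb1 11.1 and Cel 8.80, far above the other 6 control clamped arrays. The 7 basal arrays numbered 44 or higher were not the only source, since 7 of the 12 arrays lay outside them. Pancreatic tissue in the sample may be a source. Of 6 islet hormone genes, 0 passed the threshold for a rise with the acinar level, which went against it under the bound set beforehand. Their slopes were all positive, from 0.00714 ± 0.0252 (Pyy) to 0.0774 ± 0.0343 (Gcg) per log2 unit of that level. Those genes lay between 0.415 and 4.18 in every array, close to the background, so that a small share of islets would not be seen. The test therefore cannot decide, and this source stays open. The mean level was lower in clamped than in basal mice by 3.08 on the log2 scale (permutation p = 0.00494 with arrays shuffled within treatment, 0.0531 in control and 0.0456 in palm oil mice alone). The counts of arrays over 6 (9 of 16 basal, 3 of 16 clamped) gave a two-sided Fisher's exact p = 0.0659. That cut was set after the values were seen, and the fits without the 12 arrays keep arrays with a raised level. Palm oil basal replicates 2, 3 and 4 had means of 4.04, 4.75 and 3.39. Control basal replicates 4 and 5 had 5.19 and 2.995, and palm oil clamped replicate 4 had 5.275. In control clamped arrays other than replicate 3 the means lay between 1.63 and 2.53. The clamp cannot be told apart from a batch that follows the animal number.

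The 7 basal arrays numbered 44 or higher had a narrower spread and differed from the other 9 basal arrays in 2974 genes, 1295 higher and 1679 lower, in the fit with treatment. All 10 mitochondrially encoded genes measured were lower in them, with a median of -0.71 (adjusted p = 0.0164 with an estimated correlation), and insulin signalling genes passed too (4 of 24 lower, median -0.11, adjusted p = 0.0481 with an estimated correlation), while ribosomal protein genes did not (adjusted p = 0.696). A compressed range of values alone is argued against: after quantile normalization 1499 genes were called, against at most 41 in 99 other splits with the same treatments (1 of 100 gave as many, the real one), and the mitochondrially encoded genes had a median of -0.53 (median SE 0.0693), with 9 of 10 still called lower. The split was itself picked by the spread of these arrays, which can favour it over the other splits. Compression stays open for a part. Under the bound set beforehand, fewer than 1 in 3 kept, the result went with compression, as 32.65% of the 2974 stayed called, just under that bound. The median size of the 2974 went from 0.46 to 0.34 (median SE 0.12 before and after), and 528 genes were called only after quantile normalization. Acinar RNA as the whole cause is argued against, as 71.72% stayed called with the acinar level as a term; no biological explanation was tested, and the labels name no batch.

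Acute phase genes and Igfbp1 were higher in clamped mice of both treatments, although insulin is known to lower Igfbp1. The late basal arrays as the cause are argued against, since 88% of the acute phase members called in control mice stayed called without them. Insulin infusion alone is argued against for Igfbp1, whose 95% interval had a lower bound of 3.08 on the log2 scale in the treatment with the lower bound. Catheter surgery, the anaesthetic, the tracer, the later time of sampling and a batch that follows the animal number (15 to 32 in clamped, 33 to 52 in basal mice) could each contribute and stay open, since the design joins them to the clamp and no test separates them.

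Among 316 groups of values tested, which include those of the named genes and the acinar mean, 20 held an array far from the rest. Chance flags about 1 in 20 groups, which would be 15.8. Of the 20, 6 lay in control clamped replicate 6, which stood apart on the third principal component (-44.8, against -16.5 to 17.4 in the other arrays) and had the lowest median correlation within its group (0.972) of the 32 arrays, for a cause that was not tested. In control clamped replicate 6 the log2 values of Btg2 (7.07), Dhrs3 (6.25), Igfbp1 (8.57), Nfil3 (5.55) and Rdh16 (5.87) lay below the other 6 arrays of the group, and Mt2 (10.97) above them. Higher than the rest of their groups were Bcl6 in palm oil basal replicate 4 (6.71), Cyp2b9 in palm oil clamped replicate 8 (5.24), Lyve1 in palm oil clamped replicate 4 (8.01), Pdk4 in palm oil clamped replicate 6 (6.25), G0s2 in control clamped replicate 4 (5.93), Retnlg in control basal replicate 4 (2.59) and Srebf1 in control basal replicate 5 (5.54). Lower were Ddit3 in palm oil basal replicate 7 (4.32), Nfil3 in palm oil clamped replicate 2 (4.93), Pck1 in palm oil clamped replicate 4 (10.82) and Per3 in control basal replicate 7 (4.30).

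The palm oil difference itself differed between clamped and basal mice for 5 lists with the preset correlation: the unfolded protein response (adjusted p = 1.42e-06), cholesterol synthesis (0.00714), bile acid genes (0.00714), heat shock (0.00749) and beta-oxidation (0.00784), none of them with an estimated correlation, and unchanged simulated data gave 7.35 such lists on average. Of 17824 probe sets without exactly 1 gene name, 227 were called for the clamp in control mice and 186 in palm oil mice.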

How the results depend on the processing

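The block on the split of the basal arrays, the fits within its parts or without its 7 arrays, and the settings on acinar markers were chosen after the data were seen. The counts of genes for the 5 comparisons stayed within 1.5 times or, for the palm oil comparisons and the interaction, at 0 under the settings tried, with these exceptions. In control mice 1026 genes were called for the clamp without the 7 basal arrays numbered 44 or higher (795 shared with the 1940), 993 without the arrays high in acinar markers (846 shared) and 1120 with the exact rank sum test, and in palm oil mice 736 without the arrays high in acinar markers (636 shared). These settings test fewer arrays or use ranks, and no further cause was tested. Palm oil in basal mice gave 1 gene without the arrays high in acinar markers. Leaving out 1 array gave 0 to 1 genes for palm oil in basal mice (1 without control basal replicate 1 or 3), 0 in clamped mice, 0 to 1 for the interaction (1 without control basal replicate 1), 1517 to 2007 for the clamp in control mice and 1385 to 1799 in palm oil mice.

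Lists past the threshold for palm oil in basal mice numbered 0 with an estimated correlation and 0 with fry in place of 2, 5 in the brighter part of the genes, 5 with the basal array split as a block, 1 without its 7 arrays (ribosome biogenesis, neither of the 2) and 10 without the arrays high in acinar markers. In clamped mice 0 passed with an estimated correlation and 0 with fry in place of 8. For the interaction 0 and 0 passed in place of 5, and 8 in the brighter part of the genes and 8 with the split as a block. For the clamp 9 of 20 passed with an estimated correlation in control mice and 8 of 21 in palm oil mice. The cause was not tested. With the acinar level as a term the acinar list turned to an adjusted p = 0.848 in control and 0.788 in palm oil mice, by construction. Without the arrays high in acinar markers the bile acid list in basal mice (adjusted p = 0.0473), the hepatocyte list for the clamp in palm oil mice (0.933) and, for the interaction, PPARA targets (0.00990), beta-oxidation (0.691) and bile acid genes (0.849) turned direction, and the cause was not tested.

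With the replicate number as a block, 1923 and 1629 genes were called for the clamp in control and palm oil mice and 0 in the other comparisons, the correlation of the palm oil differences across genes was 0.133, and of the genes named in the text Pdk4 in palm oil mice lost its call (0.69, adjusted p = 0.0689). The titles do not state that the numbers pair mice. Deviations of arrays with the same number correlated between -0.363 and 0.360 over the pairs of groups compared. Between palm oil and control basal arrays the median was 0.0882, against -0.00135 for other numbers. Between palm oil and control clamped arrays it was -0.0623, against -0.0104. A pairing is neither shown nor excluded. Of the genes that the rule selected for the clamp in control mice, under settings fixed beforehand, other than leaving out an array, 913 of 935 values stayed on their side of the threshold, and 1036 of 1065 in palm oil mice. Under the settings chosen after the data were seen, 306 of 340 stayed in control and 332 of 388 in palm oil mice. Most of these genes were picked by size or p-value, so that the shares do not describe all genes called. Values past the threshold in neither setting count as the same. Low signal over background limits the dim genes, with a median log2 value of 1.83 over all genes.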

Other observations

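The acinar level test of further genes and the counts of unnamed probe sets were chosen after the result was seen; the lists and the rule for genes were fixed before the data were examined.

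Clock genes moved both ways between basal and clamped mice. Of 19 measured, 4 rose and 4 fell in control mice, and 5 rose and 5 fell in palm oil mice (6 and 5, and 6 and 6, adjusted over the list alone). Bhlhe40, a repressor of clock transcription, rose by 1.07 ± 0.14 and 0.79 ± 0.13 (log2, SE, n = 7 and 7, and 9 and 9), and Nfil3 by 1.43 ± 0.23 and 1.05 ± 0.20. In palm oil mice Nfil3 did not pass without the arrays high in acinar markers (0.92, adjusted p = 0.107). Per3 fell by 0.87 on the log2 scale in control mice, and Per1 rose by 0.88 ± 0.17 in palm oil mice. The list as a whole did not pass (adjusted p = 0.775 and 0.688). Clamped mice were killed at a later hour after gavage than basal mice, which the groups do not separate from the clamp.

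Among 14 endothelial markers, Lyve1, a hyaluronan receptor, rose by 1.35 ± 0.16 in control and 1.29 ± 0.14 in palm oil mice, while Kdr (-1.09 ± 0.20 and -0.78 ± 0.18) and Ehd3 (-0.68 ± 0.12 and -0.48 ± 0.10) fell. Of 15 Kupffer cell markers 4 rose in each treatment (4 and 6 adjusted over the list alone), and none fell. The list had an adjusted p = 0.0157 in control and 6.72e-04 in palm oil mice, and an adjusted p = 0.263 and 0.120 with an estimated correlation. They included the scavenger receptor Marco (1.62 ± 0.34 and 1.65 ± 0.30), which in control mice did not pass without the 7 basal arrays numbered 44 or higher (1.44, adjusted p = 0.0784) or without the arrays high in acinar markers (1.53, adjusted p = 0.0784). Among genes of xenobiotic metabolism, 5 of 23 rose and 2 fell in both treatments, also adjusted over the list alone. Tiparp, a target of the aryl hydrocarbon receptor, rose by 1.86 ± 0.26 and 1.76 ± 0.23, and Nr1i3, which encodes the receptor CAR, fell by 1.24 on the log2 scale (SE 0.22) in control mice.

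Over all 32 arrays 41 genes were associated with the mean acinar level, 38 of them positively. They include the 9 members of the list by construction, since these make up that level. Among the others were Sycn (slope 1.12 per log2 unit of that level), Reg1 (1.14) and Clps (1.02), pancreatic secretory genes singled out after their values were seen.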
